A study of Mus musculus with 2 samples.

How the data were processed

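The data were peak lists from ChIP-seq for H3K4me1 in the facial prominence of mouse embryos at embryonic day 13.5, with 2 samples that the labels call biological replicates of 1 group, each pooled from male and female embryos. Replicate 2 combined a pair of technical replicates, per the labels. Per the text deposited with the samples, the peaks were in narrowPeak format on the assembly mm10, each replicate's list was derived from its own filtered alignments, the pooled list from the alignments of both replicates, and the replicated list from both replicates' lists and the pooled list. The aligner, the peak caller, its version and threshold, the control and the overlap rule of the replicated list are not given in the sources used here. Fold enrichment, a ratio of signal over background per peak, was computed by the authors and taken as deposited. The −log10 p and −log10 q values of each peak are also the authors' values. The lowest deposited −log10 p was about 2.0 in each list, and the medians of the deposited fold enrichment were 2.97 in replicate 1, 3.09 in replicate 2, 2.74 in the pooled list and 3.14 in the replicated list. Median peak widths were 349, 368, 397 and 589 bp. The lists gave no read counts, so the depth is unknown, no interval that needs it is given, and no count model was used.

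Peaks were placed on the 21 chromosomes of GRCm38.p6, the assembly of mm10, with 2648 Mb of sequenced bases, and genes were the 21938 protein-coding genes of GENCODE vM21, with the 5' end of the gene as its TSS. A single peak of replicate 1 and of the pooled list on an unplaced sequence was left out. A peak counted as shared when at least 50% of its length was covered by the other replicate's peaks, and 100 seeded random placements on the same chromosome gave the chance value. Locations were promoter (within 1 kb of a TSS), other exon, intron and intergenic. Promoters were CpG-rich when the 500 bp on each side of the TSS had an observed over expected CpG of at least 0.6 and a GC content of at least 50%. The profile around the TSS was taken every 50 bp up to 10 kb.

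For each gene the percent of the 50 kb on each side of its TSS under merged peaks was computed, and 22 gene lists were summarised by their median: facial mesenchyme transcription factors, jaw patterning, orofacial cleft, signalling, cartilage and bone, epithelium, skeletal muscle, endothelium, blood and macrophage, neuron, Schwann cell and glia, hepatocyte, cardiomyocyte, kidney, pancreas and gut, forebrain, germ line, housekeeping, Hox genes, olfactory receptors, vomeronasal receptors and keratin-associated proteins. The lists, the motifs and the main comparison of each were fixed before the data were examined, while the GC-matched random lists, the tests of the 4-base spacing, the share of family genes without a peak, the removal of X chromosome peaks and the comparison of transcription factors were added after. Each median was compared with 10000 seeded random lists of the same size, matched on the decile of gene length and on 3 classes of the number of TSSs in the window, and called above the 97.5th or below the 2.5th percentile. P-values are two-sided permutation values with Benjamini-Hochberg adjustment over the 22 lists, and 0.0002 is the smallest possible before adjustment. A gene was densely marked when above the 75th percentile of genes in the replicated list and in both replicates' own lists (11.3%, 10.2% and 10.6%). The genes named were, by a rule fixed beforehand, the 25 highest with 1 per 100 kb cluster of TSSs, the 3 highest members and the lowest of each list that is not a gene family, the genes over the 10 longest domains, 12 genes fixed by name and any Hox gene. Genes named outside this rule are marked as chosen after their values were seen, except where they locate a peak or region.

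Replicated peaks up to 12.5 kb apart were stitched into domains. The 14 motifs were matched as consensus sequences on both strands in 135378 distal peaks (107 Mb) and in 181312 flanking windows of the same length 5 kb away (121 Mb) that touched no pooled peak and no promoter, with 1000 bootstraps of chromosomes for the 95% interval of the ratio. Reversed motifs, not complemented, served as a control of composition that keeps the base counts of a motif but not its neighbouring pairs such as CpG. For GC-matched flanks, windows were weighted in steps of 2% GC.

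The alternatives set beforehand were an overlap of 1 bp or of 50% of both peaks, only peaks with a −log10 q of at least 2, the 50000 peaks or the upper part of the replicated peaks by fold, −log10 p in place of fold, promoters of 2.5 kb, covered bases in place of midpoints, windows of 10 and 100 kb, promoter bases left out, unmatched random lists, a stitching distance of 5 kb, flanks 20 kb away, GC-matched flanks, and each replicate left out, which leaves the other replicate's own list. After the data were seen, further alternatives were added: only replicated peaks met in both replicates' own lists, X-linked genes left out, and random lists matched on GC content, also without receptor and keratin-associated genes.

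The procedures were tested on simulated data. Of 1000 lists without an effect 5.4% were called, and of 200 lists of 16 genes raised 1.5-, 2- and 3-fold over 21938 genes, 34%, 68.5% and 93.5% were called. The simulated values were independent between genes, so these rates do not cover lists whose members lie close together and share peaks. Planted motifs gave 0.997 of the planted ratio, and 7% of 200 ratios of 1 were called. The overlap procedure and a plain search differed in 0 of 6440 comparisons. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.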

Results

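H3K4me1, the monomethylation of histone H3 at lysine 4 that marks enhancers and the flanks of promoters, was mapped by ChIP-seq in the facial prominence of mouse embryos at embryonic day 13.5. At this stage the prominences, which are made of cranial neural crest mesenchyme under a surface and oral epithelium, have formed the upper and lower jaw. The series held 1 group of 2 samples, labelled as biological replicates, each from tissue of pooled male and female embryos of the strain B6NCrl. Replicate 1 had 222692 peaks covering 113 Mb and replicate 2 had 214021 peaks covering 116 Mb, on the genome build mm10. A pooled list of 241848 peaks and a replicated list of 152804 peaks accompanied them. The files gave no read counts, so the sequencing depth behind each peak was unknown. With 1 group, the design implied no contrast between conditions: it asked how far the replicates shared their peaks, where the replicated peaks lay, and which genes and sequence motifs they surrounded.

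Most of the highest peaks of each replicate were covered by peaks of the other. The peak of highest fold enrichment in the replicated list lay in an intron of Ncor2, a corepressor of nuclear receptors (chromosome 5, 125153954 to 125161409). It had a fold of 13.2 in the pooled list, 11.3 in replicate 1 and 13.2 in replicate 2. The replicated list was derived from both replicates' lists and the pooled list, so agreement of its peaks was partly built in. A peak in an intron of Rara, a retinoic acid receptor (chromosome 11, 98960492 to 98971868), had a fold of 11.2 in the pooled list, 10.2 in replicate 1 and 10.9 in replicate 2. Of the 10% of peaks with the highest fold, 98.1% in replicate 1 and 97.4% in replicate 2 were covered over at least 50% of their length by peaks of the other replicate. Of the 10% with the lowest fold, 38.6% and 32.5% were. Over all peaks the share was 60.3% for replicate 1 and 59.1% for replicate 2, against 4.76% and 4.56% for peaks placed at random on their chromosome. In 0 of 100 random placements was the share as high, and the highest was 4.87%. When only the 50000 peaks of highest fold in each replicate were set against each other, 62.0% in replicate 1 and 58.5% in replicate 2 were shared. The replicates had 77.2 Mb of covered bases in common, 68.1% of those of replicate 1 and 66.3% of those of replicate 2. Across the 131783 pooled peaks that overlapped a peak in each replicate, the folds of the replicates had a Spearman correlation of 0.566 and a Pearson correlation of 0.614 on the log2 scale. These correlations are across peaks, which are not independent replicates. The fold enrichment of a peak is the authors' own value.

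**Figure D1:**
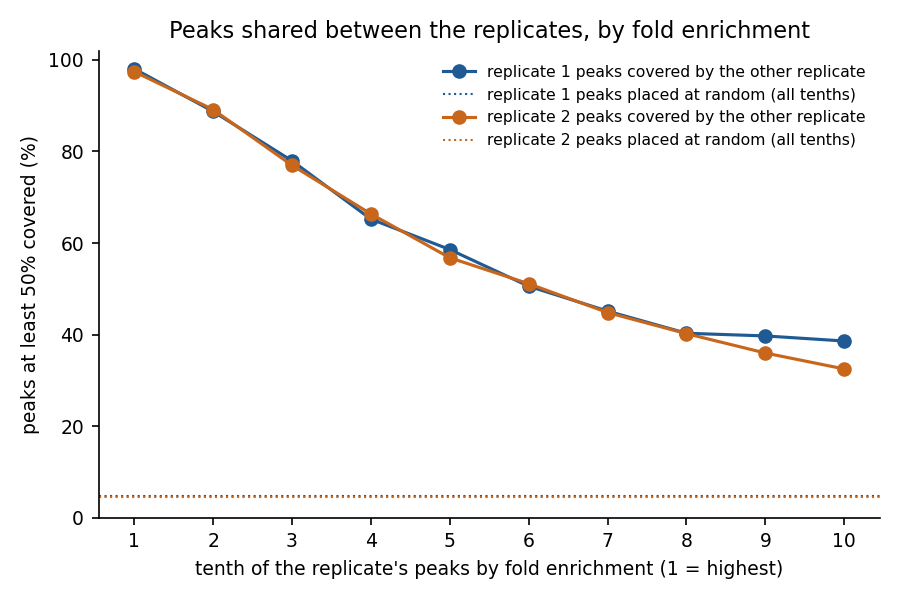
Percent of each replicate's peaks covered over at least 50% of their length by the other replicate's peaks (vertical axis), by fold enrichment in 10 classes of equal size (horizontal axis, 1 the highest). Points are the values of replicate 1 (blue) and replicate 2 (orange), which fall from 98.1% and 97.4% to 38.6% and 32.5%, and dotted lines are the means of 100 random placements of all peaks.

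The replicated list, from which the highest peaks named here were taken, held the taller and wider peaks of the pooled list. Each of its 152804 peaks was identical to a pooled peak, so that it made up 63.2% of the pooled peaks and 83.5% of their bases. The median fold was 3.14 for replicated peaks and 2.32 for the other 89044 pooled peaks, and the median widths were 589 and 245 bp. Every one of the 129350 pooled peaks that overlapped a peak of each replicate by at least 50% of either peak was in the replicated list. The remaining 23454 replicated peaks, 15.3% of the list, did not meet this overlap rule with both replicates' own lists. Of these, 10142 met it with replicate 1 alone, 12372 with replicate 2 alone and 940 with neither, and their median fold was 2.66.

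Most replicated peaks lay in introns and between genes, and the typical peak was far from the 5' end of a protein-coding gene. Promoters inside genes and those of non-coding genes were not counted as TSSs. By peak midpoint, 51.6% were in introns, against 35.1% of the genome, and 35.5% were intergenic, against 60.1% of the genome. Exons outside promoters held 5.20% of the peaks and 3.26% of the genome. Promoters, the 1 kb on each side of a protein-coding TSS, held 7.67% of the peaks and 1.56% of the genome, a ratio of 4.91. In the replicates' own lists promoters held 6.60% of the peaks of replicate 1 and 6.69% of those of replicate 2. The median distance from a replicated peak to the nearest protein-coding TSS was 36.6 kb, with 28.0% of peaks within 10 kb and 25.9% beyond 100 kb. With promoters of 2.5 kb on each side the promoter share was 15.5% and its ratio to the genome 4.06.

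CpG-rich promoters, the class that holds most housekeeping and many developmental genes, had H3K4me1 peaks beside the TSS and seldom over it. Of 9738 such promoters, 11.2% had a replicated peak over the TSS, while 60.7% had one over the position 1100 bp downstream and 39.8% over the position 650 bp upstream. The percent at the TSS was 0.184 of the highest percent within 5 kb, and 0.162 in replicate 1 and 0.184 in replicate 2. The 12200 other promoters, typical of tissue-specific genes, had no such dip. Of them, 19.4% had a peak over the TSS and at most 19.6% over any position within 5 kb, a ratio of 0.989. The ratio in the replicates' own lists was 0.998 for replicate 1 and 0.997 for replicate 2.

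**Figure D2:**
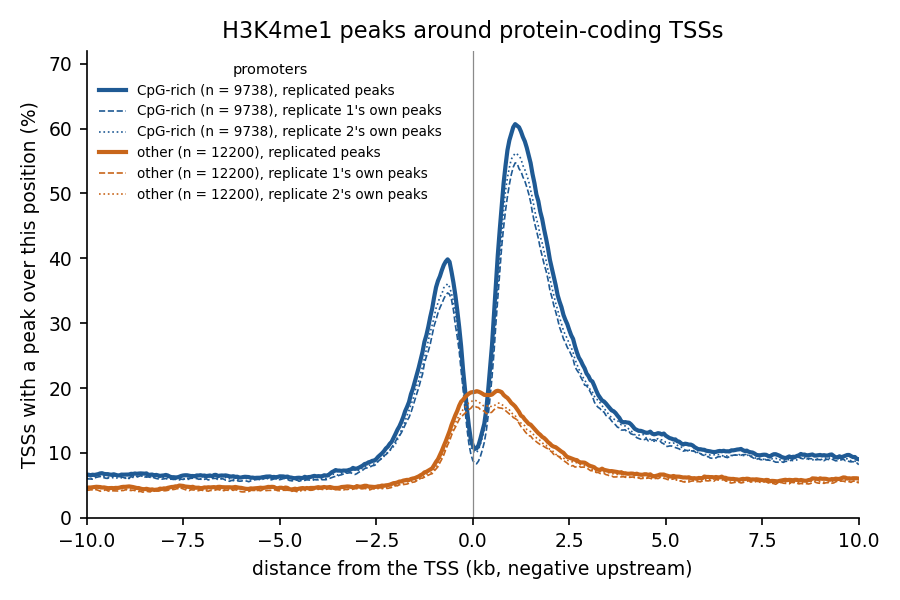
Percent of protein-coding TSSs with a peak over each position (vertical axis) by distance from the TSS in kb (horizontal axis, downstream positive), for 9738 CpG-rich promoters (blue) and 12200 other promoters (orange). Thick lines are replicated peaks, thin dashed and dotted lines the own peaks of replicates 1 and 2, and the CpG-rich profile falls to 11.2% at the TSS between shoulders of 39.8% and 60.7%.

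Transcription factor and signalling genes of the face lay in more H3K4me1 than other genes. Around each of 21938 protein-coding genes, the percent of the 50 kb on each side of the TSS under replicated peaks was taken, with a median over all genes of 5.04%. A window can hold other genes, so its peaks need not belong to the gene it is named for. The strongest peak of the Mn1 window, for example, lay in an intron of Pitpnb, while that of the Prrx1 window lay in Prrx1 itself. The list of 30 facial mesenchyme transcription factors had a median of 16.9%, and 23 of its members were densely marked, that is, above the 75th percentile of genes in the replicated list and in both replicates' own lists. Alx4, an aristaless-type homeobox gene of the frontonasal mesenchyme, had the highest value of all genes in the replicated list, 64.8%, with 56.7% ± 1.5 (SD, n = 2) in the replicates' own lists. Prrx2, a paired-type homeobox gene, had 52.2% and Pax3, a neural crest gene, 34.6%.

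Of the other facial mesenchyme genes, Prrx1 had 30.6%, Msx1 24.7%, Tfap2a 20.1% and Twist1 15.1%, and all 4 were densely marked. Satb2, at 11.6% with 13.5% in replicate 1 and 9.83% in replicate 2, and Pax9, at 9.44%, were not. The X-linked gene Tbx22, which underlies X-linked cleft palate, had no replicated peak within 50 kb. The 15 genes of jaw patterning had a median of 15.8% with 11 densely marked: Dlx3 had 35.3%, Dlx4 32.2%, Lhx6 24.01% and Dlx5 15.03%, while Nkx3-2, a gene of the jaw joint, had 3.84%. Dlx3 and Dlx4 lie close together on chromosome 11, so their windows overlap and hold the same strongest peak (fold of 7.20). The 25 signalling genes had a median of 20.99% with 17 densely marked, led by Wnt11 at 44.3%, the Wnt target Axin2 at 41.1% and Bmp7 at 36.0%, and Fgf10 was lowest at 2.29% (2.97% in replicate 1 and 1.31% in replicate 2). The 23 orofacial cleft genes, 16 of which another list also held, had a median of 12.2% with 12 densely marked. Mn1 had 47.8%, Fgfr1 32.5%, Nectin1 30.1% and Irf6, an epithelial transcription factor, 19.7%.

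The 16 genes of cartilage and bone had a median of 10.8% with 8 densely marked, from Runx3 at 36.6%, Alpl at 31.1% and Col1a1 at 29.0% to Ibsp, a gene of mineralised bone, at 2.57%. Sox9, the chondrogenic transcription factor, had 13.2% and was densely marked.

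Each list median was set against 10000 random lists matched on gene length and on the number of TSSs in the window, and called above or below them when outside their middle 95%. Of 22 lists, 6 were above and 3 below, and the Benjamini-Hochberg adjusted permutation p (two-sided) was over the 22 lists. The facial mesenchyme, jaw and signalling lists were above all 10000 random lists, whose median values were 3.42%, 2.67% and 4.19%, with an adjusted p of 0.00088, from the smallest permutation p possible, 0.0002. The cleft list was at the 99.98th percentile (adjusted permutation p = 0.0022) and the cartilage and bone list at the 99.22nd (adjusted permutation p = 0.0434). Genes are not replicates, so these percentiles describe these libraries. Neighbouring members such as Dlx3 and Dlx4 share peaks, and the random lists, drawn gene by gene, do not copy this. The covered percent followed the GC content of the window across genes (Spearman 0.770). With random lists matched on GC content and TSS number, the facial mesenchyme list was at the 100th percentile, jaw at 99.96, signalling at 100 and cleft at 99.18 (adjusted permutation p = 0.0739), and cartilage and bone was at 97 and no longer called.

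**Figure D3:**
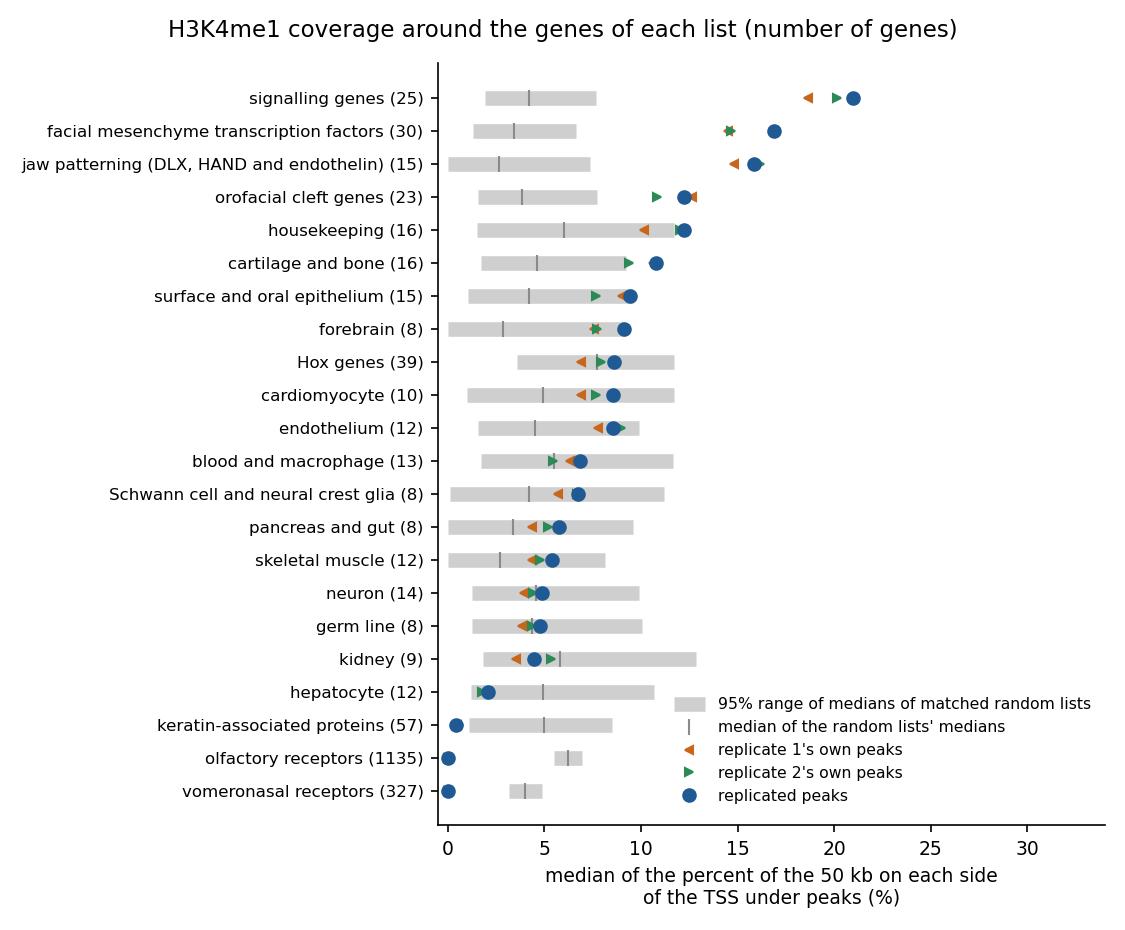
Median over the genes of each list of the percent of the 50 kb on each side of the TSS under peaks (horizontal axis), with the list and its number of genes on the vertical axis. Blue circles are replicated peaks, triangles the own peaks of replicate 1 (orange) and replicate 2 (green), grey bars the 95% range and grey ticks the median of matched random lists, and the signalling, facial mesenchyme, jaw and cleft lists lie to the right of their bars.

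With windows of 50 kb, genes of the other cell types of the face were closer to their random lists. With windows of 10 kb the epithelial, skeletal muscle and glial lists were called above. The 15 epithelial genes had a median of 9.42% (percentile 97.2), with Grhl3 at 28.3% and Cdh1, the epithelial cadherin, at 17.1%, and with Trp63, the master gene of stratified epithelium, at 0.982% (1.89% in replicate 1 and 0.972% in replicate 2). Trp63 is 208340 bp long and its window reached only 50 kb into the gene, so any promoter further inside was not measured. The 12 skeletal muscle genes had a median of 5.38% (percentile 87.2), with Tbx1 at 28.4% and Myh3, the embryonic myosin, at 2.63%. The 12 endothelial genes had 8.54% (percentile 93.9), with Fli1 at 37.3% and the receptor gene Tek at 1.55% (0.790% in replicate 1 and 1.69% in replicate 2). Blood and macrophage genes had 6.86% (percentile 69.4), with Fcer1g at 23.2%, where the strongest peak of the window lay in an exon of Ppox. Schwann cell and glial genes had 6.73% (percentile 79.0), with Sox10 at 15.1%, and neuronal genes had 4.87% (percentile 55.8), with Prph at 22.1%.

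In the main comparison, with windows of 50 kb, genes of organs outside the face had medians inside their random range. This depended on the setting: with windows of 10 kb the cardiomyocyte and forebrain lists were called above. The forebrain list was also called with only peaks of a −log10 q of at least 2. Hepatocyte genes had 2.10% (percentile 8.27), with Alb, the serum albumin gene, at 0.757% and no peak around Serpina1a. With random lists matched on GC content the hepatocyte list was at the 2.34th percentile and called below, with an adjusted permutation p of 0.172. Kidney genes had 4.48% (percentile 28.8), with no peak around Umod. Pancreas and gut genes had 5.75% (percentile 80.9), with Cdx1 at 26.7% and Ins2 at 0.802%. The strongest peak of the Cdx1 window lay in an intron of Pdgfrb. Cardiomyocyte genes had 8.55% (percentile 87.5), with Myl7 at 16.6%, germ line genes 4.75% (percentile 57.8), and forebrain genes 9.14%, at the upper edge of the middle 95% and so not called, with Emx2 at 19.5%. The 16 housekeeping genes, with Rplp0 at 33.1%, had 12.2% and were above their random lists at the 98.4th percentile. Their adjusted permutation p was 0.0792, and the call ended with GC-matched lists (95.8), without X-linked genes (96.4) and in the own peaks of replicate 1 (96.9). It also ended with random lists matched on CpG-rich promoters and gene length (94.4).

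Chemosensory receptor and keratin-associated protein genes had the least H3K4me1. Of 1135 olfactory receptor genes 969 had no replicated peak within 50 kb, of 327 vomeronasal receptor genes 300, and of 57 keratin-associated protein genes 25. Their medians were 0%, 0% and 0.435%, at the 0th, 0th and 0.25th percentile of matched random lists (adjusted permutation p = 0.00088, 0.00088 and 0.017). With random lists matched on CpG-rich promoters and gene length, both receptor families stayed at the 0th percentile (adjusted permutation p = 0.0011). The keratin-associated genes were then at 43.5 and not called. The genes of the 3 families lie in clusters of low GC content. Against lists of the same GC content and TSS number drawn from genes outside the 3 families, they were at the 50th, 5.11th and 2.82nd percentile and not called. For the receptors that comparison could not have given a call, since their medians and the lower edge of the middle 95% of random medians were all 0%. The share of genes without a peak, a comparison added after the values were seen, was higher for the receptors. It was 85.4% against 62.8% of such other genes for the olfactory match and 91.7% against 46.7% for the vomeronasal match. Both were above all 10000 random lists (permutation p = 0.0002). For the keratin-associated match it was 43.9% against 37.6% (permutation p = 0.298). Clustered genes share windows, while the random lists were drawn gene by gene and so spread too little. The permutation p-values of these families are therefore likely too small.

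The Hox genes, which are silent in the neural crest in front of the second pharyngeal arch, had a median of 8.62% (percentile 67.0), and the clusters differed. The HoxD cluster on chromosome 2 had a median of 15.7% over 9 genes and held all 8 densely marked Hox genes, with Hoxd8 highest at 18.5%. The HoxA cluster had 10.5%, with Hoxa2 at 8.62%, HoxC 5.53% and HoxB 5.27%, with Hoxb13 lowest at 1.73%. Against lists of the same GC content and TSS number, the Hox list was at the 0.02nd percentile (adjusted permutation p = 0.0044) and called below. Neighbouring Hox genes share most of their windows, so that the 39 values are not independent.

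Alx4 headed the 25 gene neighbourhoods with the densest marking in the replicated list, but not in every list or window. In the own peaks of replicate 2 it had 55.6%, below G430095P16Rik at 57.5%, Nxn at 56.6% and Tcf20 at 55.9%, and within 10 kb it had 51.0% and G430095P16Rik 84.5%. In the replicated list it was followed by G430095P16Rik at 60.4%, Tcf20 at 59.8%, Nxn at 59.1%, Mrpl23 at 58.6%, Synpo at 57.4% and Gse1 at 56.6%. The corepressor gene Ncor2 had 56.4%, the retinoid receptor genes Rara 52.7% and Rxra 50.4%, the SMAD repressor gene Ski 55.5%, the inhibitory Smad7 49.9% and Pmepa1 50.7%. Also among them were the neural crest receptor gene Ngfr at 48.8%, the Groucho-type corepressor gene Tle3 at 50.02%, Bcl11b, a zinc finger gene, at 48.7% and the extracellular matrix gene Fbln2 at 52.8%. No test was made of what these genes have in common. Across all genes the replicates' own values had a Spearman correlation of 0.989.

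The peaks around Alx4 formed 1 of the longest domains of the mark. Neighbouring peaks were stitched into 33032 domains, of which 573 were at least 100 kb long. The domain over Alx4 (chromosome 2, 93418332 to 93822895) was 405 kb long, the sixth longest, held 149 replicated peaks over 42.0% of its length, and also overlapped Cd82 and Ext2. Its highest peak (93661085 to 93665184), in an intron of Alx4 and of Ext2, had a fold of 8.92 in the pooled list, 8.03 in replicate 1 and 8.55 in replicate 2. The longest domain, over Rad51b and Zfp36l1 (chromosome 12, 79598134 to 80148221), was 550 kb long, and the next were over Gse1 at 549 kb, Ncoa3 and Sulf2 at 495 kb, and Wnt11, Uvrag and Dgat2 at 463 kb. Domains over Auts2 (410 kb), Fgfr2, the FGF receptor gene of craniosynostosis (398 kb), Msi2 (381 kb), Tfeb, Mdfi and Foxp4 (363 kb) and Iqca and Ackr3 (358 kb) completed the 10 longest. The number of long domains depended on the stitching distance, with 28 of at least 100 kb at 5 kb, and on the peaks used, with 151 for the 76402 replicated peaks of highest fold. So did the length of the longest, which was 849 kb in the own peaks of replicate 1 and 593 kb in those of replicate 2, and the order given here is that of the replicated list.

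**Figure D4:**
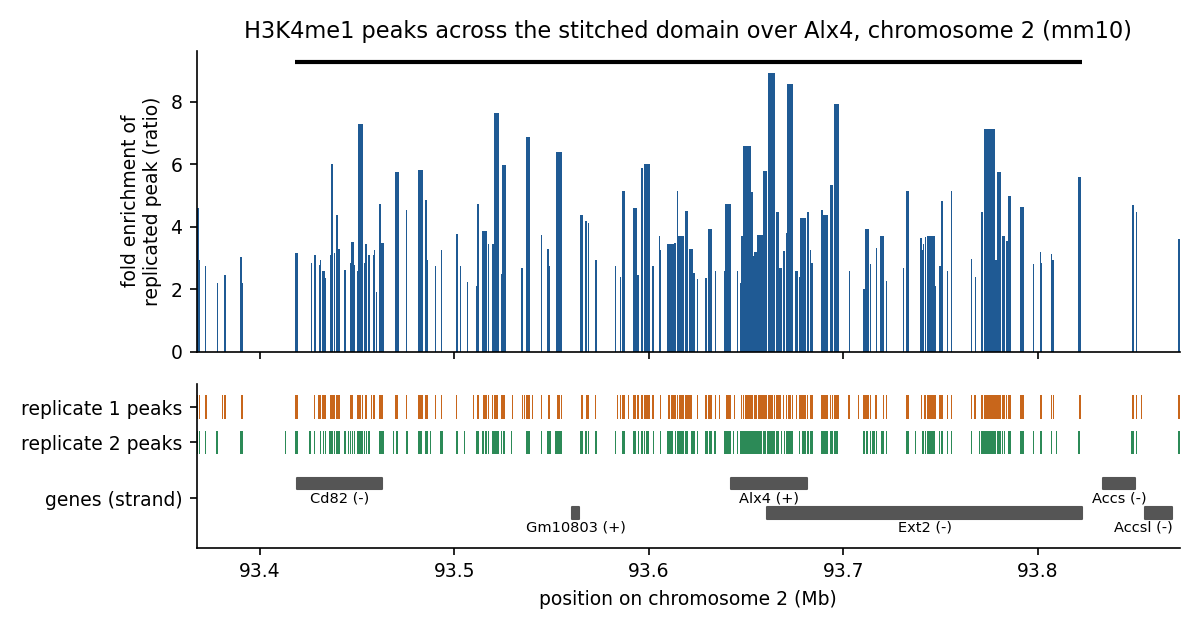
Replicated H3K4me1 peaks over and around the stitched domain at Alx4 on chromosome 2 of mm10, with position in Mb on the horizontal axis and the fold enrichment of each peak (ratio) on the vertical axis; the black line is the domain, from 93418332 to 93822895. Below are the own peaks of replicate 1 (orange) and replicate 2 (green) and the protein-coding genes with their strand, and the tallest peak, with a fold of 8.92, lies where Alx4 and Ext2 overlap.

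Distal peaks held more sites of TFAP2, MEF2, TEAD, AP-1 and FOX factors and more TWIST-type E-boxes than their flanks, and of the reversed motifs that served as a control only those of TFAP2 and TEAD were also above with the nearby flanks. In the 135378 replicated peaks further than 1 kb from a TSS, matches per kb relative to flanking windows 5 kb away had a ratio of 2.03 for TFAP2 (95% bootstrap interval 1.97 to 2.07), 1.49 for MEF2 (1.38 to 1.62), 1.22 for TEAD (1.21 to 1.24) and 1.203 for the E-box CATCTG (1.189 to 1.218). CTCF, the insulator protein, had 1.54 (1.38 to 1.74), AP-1 1.09 and FOX 1.07. Homeobox (TAATTA, 0.748), HOX-PBX (0.712), GATA (0.855) and SOX (0.910) sites were rarer in peaks than in flanks. Matches of HNF4, a factor of liver and gut, had a ratio of 0.949 and an interval that included 1. REST had 5 matches, too few for a ratio. The joint site of an E-box and a homeobox 6 bases apart, after the Coordinator motif bound by TWIST1 with homeodomain proteins, had a ratio of 1.01 (0.904 to 1.14). Of 14 motifs, 7 were above and 4 below.

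The base composition of the peaks turned some of these directions. Peaks had a GC content of 49.1% and flanks 44.2%. Against flanks of the same GC content, homeobox sites had a ratio of 1.36, HOX-PBX sites 1.26 and SOX sites 1.06, with GATA at 1.02 and an interval that included 1, while CTCF fell to 1.00 and was no longer called. The E-box and homeobox site had a ratio of 1.51 (1.31 to 1.76), MEF2 2.27, FOX 1.37, TFAP2 1.23, TEAD 1.18 and the E-box 1.101. Then 10 of the 14 motifs were above and 0 below. As a control of composition the same motifs were read reversed: 2 of them were above with the nearby flanks and 6 with the GC-matched ones. The reversed TFAP2 motif had higher ratios than the motif itself, 3.05 and 1.44, and the reversed SOX motif 0.997 and 1.19. Reversed, the TFAP2 motif reads CGGNNNCCG, with fixed CpG pairs that the motif lacks. In flanks 5 kb away it had 0.0132 matches per kb, against 0.184 for the motif. It is therefore a poor control for TFAP2, and its ratios do not settle whether composition accounts for the TFAP2 excess. Reversed MEF2 had 0.798 and 1.46 (1.25 to 1.74), and reversed FOX 0.843 and 1.17 (1.15 to 1.19), so with GC-matched flanks part of the excess of these motifs was also met without their sequence. The reversed E-box had 0.709 and 0.722, the reversed homeobox site 0.577 and 1.079, and the reversed TEAD motif 1.03 and 0.988. The reversed joint site of E-box and homeobox had 0.635 and 1.11 (0.836 to 1.51).

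**Figure D5:**
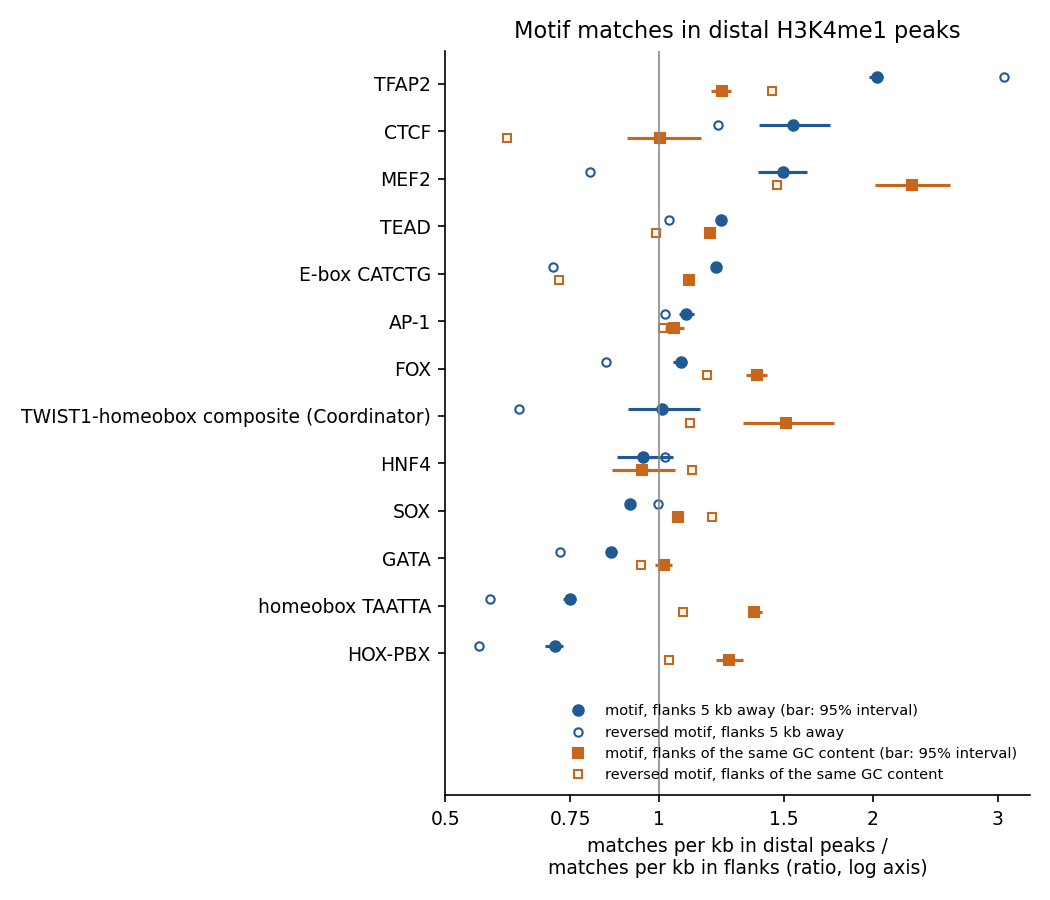
Matches per kb in distal replicated peaks divided by matches per kb in flanks (horizontal axis, log scale) for 13 of the 14 motifs, named on the vertical axis. Filled symbols are motifs with their 95% bootstrap interval, open symbols the reversed motifs, blue for flanks 5 kb away and orange for flanks of the same GC content, and the homeobox site moves from 0.748 to 1.36 between these flanks.

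Genes on the X chromosome had little H3K4me1 in these lists. The X chromosome held 849 replicated peaks, 5.19 per Mb, against 63.4 per Mb on the autosomes, a ratio of 0.0819, and 0.304% of its bases were covered against 5.13%. Among the autosomes chromosome 14 was lowest at 50.7 per Mb and chromosome 11 highest at 89.8 per Mb. In the replicates' own lists the X chromosome held 0.0904 of the autosomal density in replicate 1 and 0.0845 in replicate 2. Of 948 protein-coding genes on it, 592 (62.4%) had no replicated peak within 50 kb, against 15.7% of autosomal genes. Among the lists, 8 members were X-linked and 6 of them had no replicated peak: Tbx22, Plp1, Gata1, Alas2, Tex11 and Dcx, of which Gata1 was named after its value was seen. The Y chromosome had 0 peaks. Without X-linked genes in the lists and random lists, the facial mesenchyme median was 18.2%, again at the 100th percentile.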

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

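With 2 replicates and no read counts, the depth limits how far weak peaks can be judged, and where a value moved the cause was not tested unless the alternative's own construction shows it. Alternatives chosen after the data were seen were the peaks met in both replicates' own lists, the lists without X-linked genes and the GC-matched random lists. Of the main values under all alternatives, 321 kept their direction and side of the threshold or stayed within the spread, 12 were weaker, 12 stronger, 18 moved and 28 had the other direction, most of the last for lists or motifs that were not called, which passed their midpoint without a call. REST, with at most 6 matches in peaks and intervals that all included 1, is read in no direction: its ratio was 0.998 with the peaks of highest fold, 0.768 with flanks 20 kb away and 0.601 with GC-matched flanks. The facial mesenchyme, jaw, cleft and signalling lists were called under all 11 alternatives each, with lowest percentiles of 99.99, 99.96, 99.18 and 100. Overlap of the replicates stayed above all random placements under the 4 alternatives. Of 840 values of 105 named genes, 517 moved by more than the spread between replicates.

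For the replicates and the pooled list, the correlation was 0.555 at a −log10 q of at least 2 and 0.603 for −log10 p, and the replicated list made up 66.6% of pooled peaks at a −log10 q of at least 2. Overlap by 1 bp with a peak of each replicate's own list, another measure than the deposited list, was met by 54.5% of pooled peaks. With the replicated peaks of highest fold, promoters held 9.71%, the dip ratio was 0.162, the X to autosome ratio 0.0493, domains of at least 100 kb numbered 151, the epithelial list rose to 97.6 and was called, and the Hox list (29.4), HNF4 (1.00) and the E-box and homeobox site (0.995), none of them called, passed their midpoint. With only the peaks met in both replicates' own lists, promoters held 8.18% and the X ratio was 0.0728. Promoters of 2.5 kb held 15.5% of peaks by construction. Stitching at 5 kb gave 57355 domains and 28 of at least 100 kb, also by construction. With a −log10 q of at least 2 the forebrain list, at 97.6, was called.

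With windows of 10 kb, 11 lists were above: glia (98.6), cardiomyocyte (98.8), forebrain (98.6), muscle (99.6) and epithelium (99.7) became called, keratin-associated genes (12.51) were no longer called, and blood (17.5), endothelium (46.5) and germ line (5.90) turned. With windows of 100 kb endothelium (98.7) became called and blood (34.1), germ line (34.5) and neuron (35.8) turned. With promoter bases left out neuron (48.5) turned. With unmatched lists Hox (98.0) became called and germ line (44.5) and neuron (46.4) turned. Without X-linked genes housekeeping (96.4) was no longer called. With GC-matched lists cartilage and bone (97), housekeeping (95.8), olfactory receptors (50), vomeronasal receptors (48.7) and keratin-associated genes (17.1) were no longer called, which for the receptors was bound to happen because their range of random medians began at 0%, hepatocyte (2.34, adjusted permutation p = 0.172) became called below, and Hox (0.02), blood (36.5), cardiomyocyte (11.5), pancreas and gut (28.8) and muscle (31.0) turned. Drawn from genes outside the families, such lists put the 3 families at 50, 5.11 and 2.82, not called, for the receptors again with a range that began at 0%.

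With GC-matched flanks CTCF (1.00) was no longer called, the E-box and homeobox site (1.51) became called, HOX-PBX (1.26), SOX (1.06) and homeobox (1.36) turned, and GATA (1.02, interval including 1) was no longer called.

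With each replicate left out in turn, the ranges were 6.60% to 6.69% for promoters, 0.162 to 0.184 for the dip ratio, 0.0845 to 0.0904 for the X ratio and 0.957 to 1.00 for HNF4, and in percentiles 96.9 to 99.1 for housekeeping, 93.0 to 98.1 for epithelium, 47.1 to 63.7 for Hox, 44.6 to 54.7 for germ line and 43.3 to 50.7 for neuron. Where a call changed, it was without replicate 2.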

Other observations

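Tests chosen only after a result was seen include the removal of X chromosome peaks whatever their height, the comparison with transcription factors of other organs and cell types, and the share of receptor and keratin-associated genes without a peak. The spacing of 4 bases was found in the data and then tested on them, with the choice on 1 set of chromosomes and the measurement on the other added later, and random lists matched on GC content were added after the covered percent was seen to follow it.

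The 10 highest single peaks of the replicated list are given here with their fold in the pooled list, and the genes of this paragraph were chosen after their values were seen. After the peak in Ncor2 came peaks in introns of Vgll4, a TEAD cofactor gene (fold of 11.7 in the pooled list, 12.9 in replicate 1 and 9.64 in replicate 2), Rara (11.2), and Fto (10.9), whose introns are known to hold enhancers of Irx genes. Introns of Gli2, a Hedgehog effector (10.8), Ahdc1 (10.5), Lrp1 (10.5), Thra, a thyroid hormone receptor gene (10.3), and Prdm11 (10.3) held the others, and 1 peak (chromosome 10, 81568320 to 81570901) was intergenic, with a fold of 6.62 in replicate 1 and 12.7 in replicate 2. The peak in Ahdc1 (chromosome 4, 133039150 to 133057081) was the widest of them at 17932 bp.

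Few peaks lay on the X chromosome, at 0.0819 of the autosomal density. Autosomal bins of 1 Mb with the same GC content and number of TSSs held 5.20 times the peaks per Mb of the X bins (5.09 to 5.37 with each autosome left out), which argues against base composition and gene density as the whole cause. Removal of X peaks whatever their height, as the whole cause, is argued against by the folds of the pooled peaks that were listed there, whose 95th percentile was 0.734 of the autosomal one (interval 0.712 to 0.752). These folds cannot tell whether peaks were removed in addition to a lower signal on the X chromosome. A candidate explanation that stays open is fewer active copies of the X chromosome in this pool of male and female embryos: the 95th percentile over CpG-rich promoters of the highest fold within 5 kb was 3.69 on the X chromosome and 6.71 on the autosomes, a ratio of 0.550 (interval 0.519 to 0.590), inside the range from 0.4 to 0.75 set beforehand. No biological explanation was tested between groups, since the design gives none that differ in X chromosomes.

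The facial mesenchyme, jaw, cleft and signalling lists lay above random lists. GC content as the whole cause is argued against, because with GC-matched lists the lowest of the 4, cleft genes, stayed at the 99.18th percentile (adjusted permutation p = 0.0739), and so are CpG-rich promoters, since with lists matched on these and gene length the lowest, jaw patterning, was at 99.06 (adjusted permutation p = 0.0597). For cartilage and bone the GC match ended the call: the median of 10.8% met random medians of 6.41% in place of 4.62%, at the 97th percentile, so that GC content may account for part of it, while the match on CpG-rich promoters left it at 99.47. Dense marking of any developmental transcription factor is argued against by the 29 autosomal facial factors, whose median of 18.2% stood above 6.82% for 33 factors of other organs, neurons and blood, 6.30% for the 23 of other organs alone and 7.04% for 53 with those of muscle, endothelium, glia and epithelium added (highest two-sided permutation p = 0.0002). The facial and other factors were not matched on GC content, gene length or number of TSSs, so part of the difference may come from these. A link of the facial factors' marking to the identity of the tissue is a hypothesis that was not tested against another tissue, since the series holds 1.

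The E-box and homeobox site, fixed at 6 bases apart before the data were seen, had a GC-matched ratio of 1.51, and a fixed spacing of 6 is argued against because the ratio at 4 bases was 3.06 (interval 2.76 to 3.46), with 1.28 to 1.78 at the other 20 of 21 spacings. That 4 was the highest of 21 by chance is argued against because of the odd and the even chromosomes, each taken alone, 0 had another highest spacing, and the spacing chosen on the odd ones had 3.05 on the even (2.67 to 3.58, next 1.76) and that chosen on the even 3.08 on the odd (2.65 to 3.63, next 2.00), and copies of 1 repeat by the ratio of 3.66 outside repeat-masked bases (3.21 to 4.22), where the next spacing had 2.31. Matches in repeats were left out while the window lengths were kept, and the ratios at the other spacings rose as well. The value of 3.66 is therefore read against 2.31 and not against 3.06. The types of E-box, read towards the homeobox site, were counted without a match on GC content and without a test. At 6 bases CATCTG made up 8.85% of the matches in peaks and 6.01% of those in flanks, and CAGCTG 10.4% and 6.19%. At 4 bases the 903 matches in peaks had CATCTG in 11.4% of cases and those in flanks in 3.29%. There its other orientation CAGATG had 6.202% and 6.399%, and CAGCTG 9.52% and 3.11%. Such matches lay in distal peaks within 50 kb of 4 of the 30 facial mesenchyme factors, Alx1, Alx3, Msx1 and Osr2 (named after their values were seen), percentile 89.82 of random lists with the same covered percent, so that a placement near these genes was not seen beyond chance; the match near Osr2, CAATTAAAAACAGATG (chromosome 15, 35269497 to 35269512), was intergenic and 26.6 kb from its TSS. Joint binding of an E-box and a homeodomain protein at this spacing is a hypothesis that may explain the excess, found on the same peaks, and binding itself was not tested.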
